A study of Caenorhabditis elegans with 2 samples.

How the data were processed

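The data are transcription factor ChIP-seq peak lists from whole Caenorhabditis elegans larvae at the L2 stage, of mixed sex. Per the labels, the strain OP355 carries the unc-119(tm4063) mutation and the integrated transgene wgIs355, which targets mdl-1, and chromatin was fragmented by sonication. Both samples are biological replicates of 1 group, and no second condition was analysed here, so no comparison between groups was made. The target protein is given as MDL-1 in the labels for the antibody, the strain and the experiment, while a further label on the same samples names KLU-1 as the protein fused to a GFP-FLAG tag at its C terminus. Samples were grouped by the first of these, and the disagreement was carried into the tests.

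Per the text files deposited with each replicate, the lists were made from each replicate's alignments together with 1 further file, presumably the control experiment that the labels name as possible, once for each of 2 genome builds, ce10 and ce11. For each build the authors gave a list of 30000 peaks and background regions per replicate, a list of 30000 regions from the pooled replicates, and an optimal list kept after thresholding on the irreproducible discovery rate (IDR), which measures how consistently ranked regions recur between replicates. The aligner, the peak caller, its version and the IDR threshold are not given in the sources used here. Each region carries a deposited signal value from the authors' caller, whose scale is not stated, and a deposited −log10 q-value. The signal was used only to rank regions within a list and to describe them, and levels were compared between lists only for the same ranks in ce10 and ce11 and for the same peaks in both replicates. The −log10 q-value was not used for ranking, because 643 of the 1076 optimal ce11 peaks were tied at its maximum of 3.11. Read counts per library were not analysed here, so the sequencing depth is unknown. The precision given below comes from the number of peaks and from the spread between the 2 replicates, and intervals on shares are exact (Clopper-Pearson) 95% binomial intervals, which cover counting error only.

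All positions are ce11 positions, counted from 1. Gene models were those of Ensembl release 115 for the same assembly, with 19973 protein-coding genes on the 6 nuclear chromosomes, and sequence was read from the reference genome of that assembly. The ce10 lists were compared with the ce11 lists only as ranked lists, and no coordinate was converted between builds. The summit is the position in each region that the authors' caller marked as its highest point. A promoter window ran from 1000 bp upstream to 200 bp downstream of any annotated start of a protein-coding transcript. A base that several annotations covered was counted, in this order, as coding exon, 5′ UTR, 3′ UTR, intron of a protein-coding gene, gene of another biotype or intergenic.

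The optimal ce11 list, with 1076 peaks, was the main list. To give each result a value per replicate, the 1076 regions with the highest signal in each replicate's own list were analysed in the same way. Agreement between replicates was the share of these regions that overlapped a region of the other replicate by at least 1 bp, set against 1000 random placements of one list within chromosomes. Shares of summits in an annotation were set against 10000 random placements of the summits on their own chromosomes, in two-sided permutation tests whose smallest possible p was 0.0002. Shares per chromosome were set against the share of protein-coding genes in two-sided exact binomial tests. CACGTG, the E-box of the bHLH-Zip family to which MDL-1 belongs, was sought within 50 bp of each summit and in windows of the same width centred 300 bp to each side, with a two-sided exact McNemar test against the left flank. All 2080 6-mers, with reverse complements merged, were tested likewise. Genes were linked to a peak when its summit lay in their promoter window. For 30 gene lists fixed beforehand, the share of genes with a promoter peak was compared with that of all other protein-coding genes by two-sided Fisher's exact tests. Adjusted p-values are Benjamini-Hochberg values within each family of tests, and the threshold was 0.05. Of the list members written down, 6 symbols matched no gene in the annotation and were left out. Lists defined by a symbol pattern take every gene whose name matches.

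Named genes followed a fixed rule. They were the protein-coding genes whose promoter window held the summit of 1 of the 15 strongest optimal peaks or of the 10 strongest with CACGTG, up to 4 members per gene list with the strongest promoter peak, and always mdl-1, mxl-1, mxl-2, mxl-3, mml-1, klu-1 and unc-119. Other genes are named only where the text says that they were chosen after their values were seen. The groups, the main tests, the gene lists and the alternatives were fixed before the data were examined. The shares of introns, exons, UTRs and intergenic sequence, the classes of non-coding RNA genes, the regions below the authors' threshold, the tests of explanations for the X share and all analyses of GACGCA and of peaks without CACGTG were added later.

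The promoter share, the E-box share, the 6-mer scan, the gene lists and the replicate agreement were first tested on simulated data. Among 200 sets of 1076 randomly placed summits, 7.5% gave a promoter p under 0.05, and a planted promoter share of 51.3% was found as 51.4%. When CACGTG was written into 20.2% of 1076 random windows, the motif test found it in 21.4% of them against 1.53% of flanks, and the scan of 2080 6-mers ranked it 1. With nothing planted, 2 of the 2080 6-mers passed the threshold. These windows lay at random positions, so they lacked the difference in base composition that real summits have from their flanks. Random target genes among the 19973 gave any list past the threshold in 5% of 200 sets, and a list in which 20% of members were targets passed in 100% of them. Those genes were drawn independently, whereas a real peak can be linked to several genes. For replicate agreement, a shifted copy that kept 71.2% of 1076 regions was found to share 71.7%. Alternatives covered the promoter window, the kind of gene, the position within the peak, the motif window and its control, the assignment of peaks to genes, the background of the gene lists, a stricter set of peaks, the peaks around mdl-1 and unc-119, and each replicate's own list in place of the optimal one. The work used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.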

Results

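The series measured where MDL-1 binds the genome of L2 larvae of C. elegans. MDL-1 is a bHLH-Zip transcription factor of the Mad type, a family that pairs with Max-like partners and recognises the E-box CACGTG. The larvae were whole animals that carried a tagged transgene, in 2 biological replicates of 1 group. The optimal list held 1076 peaks in ce11, with a signal from 48.3 to 1134 and a median of 72.5 in the authors' units. Most peaks, 917, had a width of 340 bp, and the widest spanned 580 bp. These 1076 peaks were the top of the pooled list of 30000 regions when ranked by signal. The ce10 list held 1075 peaks, of which 706 matched the ce11 peak of the same rank in chromosome and width, and signals differed by at most 0.923% rank by rank, so only ce11 is described below.

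The strongest signal in the genome lay at mdl-1 itself. Peak 1, at X from 6741916 to 6742495, had a signal of 1134 and an intergenic summit 94 bp from the start of mdl-1. Peaks 2 and 3, with signals of 1054 and 764, lay at X from 6737415 to 6737960, in intergenic sequence, and at X from 6750147 to 6750543, in an intron of another protein-coding gene. All 3 held CACGTG within 50 bp of the summit, and they ranked 1, 2 and 3 in both replicates' own lists. Within 20 kb to each side of mdl-1 there were 17 optimal summits, of which 6 had CACGTG, spread over 21.0 kb. They made up 1.58% of the peaks and 5.73% of the summed signal, and their median signal was 234 against 72.1 for all other peaks.

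**Figure D1:**
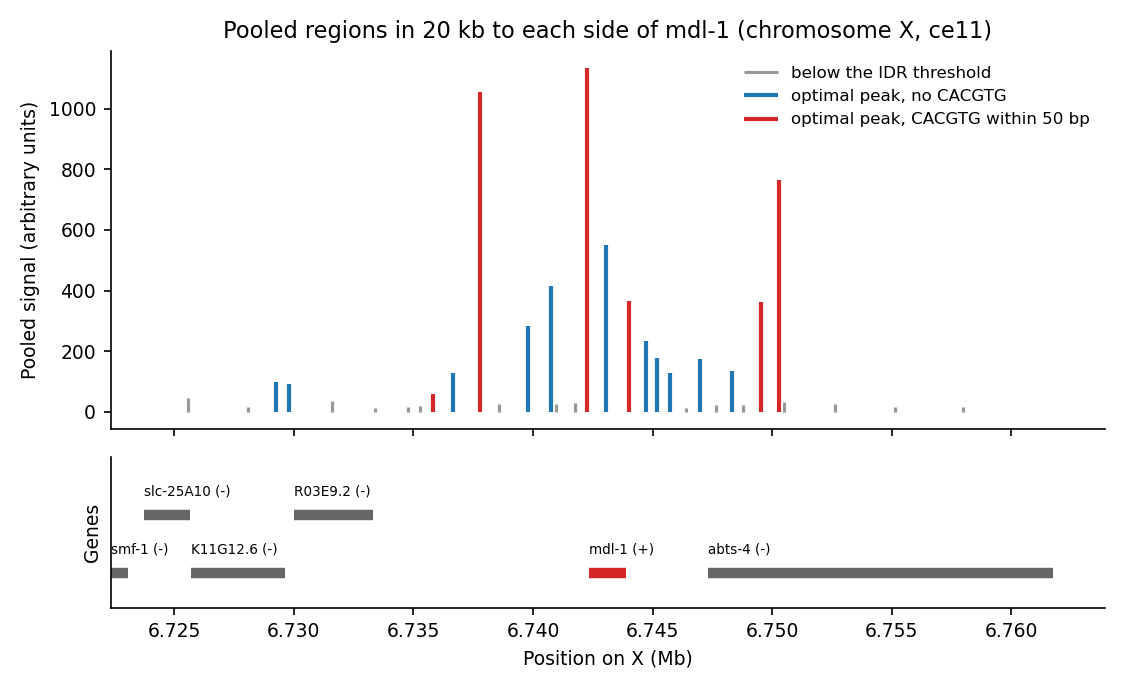
Pooled signal (arbitrary units, upper panel) of regions against position on X in Mb, with protein-coding genes and their strand in the lower panel. Coloured lines are the 17 optimal summits, red with and blue without CACGTG within 50 bp, and grey lines are regions below the IDR threshold; the 3 highest lines, all red, have signals of 1134, 1054 and 764.

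No other protein-coding gene had more than 17 optimal summits in the same window, and the median gene had 0. In the replicates' own lists the mdl-1 window held 22 summits in replicate 1 and 17 in replicate 2. The window around klu-1, the zinc-finger gene that 1 label names as the tagged protein, held 0 optimal summits. The window around unc-119, the rescue marker of the strain, also held 0. A transgene adds copies of the genes it carries, so signal at mdl-1 need not come from the native locus.

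Beyond the mdl-1 window, the strongest peaks were mostly outside promoter windows of protein-coding genes. Peak 4, at III from 12583551 to 12583802, had a signal of 725 and held CACGTG in intergenic sequence 8281 bp from the nearest protein-coding start. Peak 6, at IV from 11956360 to 11956659, had a signal of 608 and held CACGTG inside a non-coding RNA gene. Among the 15 strongest peaks, 4 had a summit in the promoter window of a protein-coding gene. Apart from mdl-1 these genes were epn-1, which encodes the endocytic adaptor epsin, nipi-3, a Tribbles-like kinase gene of innate immunity, and T28B11.1. The epn-1 peak, at X from 14818809 to 14819143, had a signal of 585 and no CACGTG. The nipi-3 peak, at X from 15607546 to 15607804, had a signal of 407 and no CACGTG. The T28B11.1 peak, at V from 10715833 to 10716122, had a signal of 410 and held CACGTG in an intron. Peaks 5 and 14, outside promoter windows, lay 1049 and 1051 bp from the nearest protein-coding start, close to the 1000 bp limit. Among the stronger peaks of the whole list the promoter share was 49.4%, near the 50.1% of all peaks.

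The replicates shared most of their strongest regions. Of replicate 1's 1076 strongest regions, 713 overlapped one of replicate 2's, which is 66.3% (95% interval 63.4 to 69.1). Random placement gave 0.734% on average and at most 1.77% in 1000 permutations, so that p = 0.001, the smallest value these permutations can give. Across all 1070 optimal peaks found in both full lists, Spearman's rho of the signal was 0.61. This correlation is across peaks, which are not independent replicates. The pooled list was chosen on signal from both libraries, which shapes rho near its lower end, where it was -0.384 among the 533 weaker peaks.

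**Figure D2:**
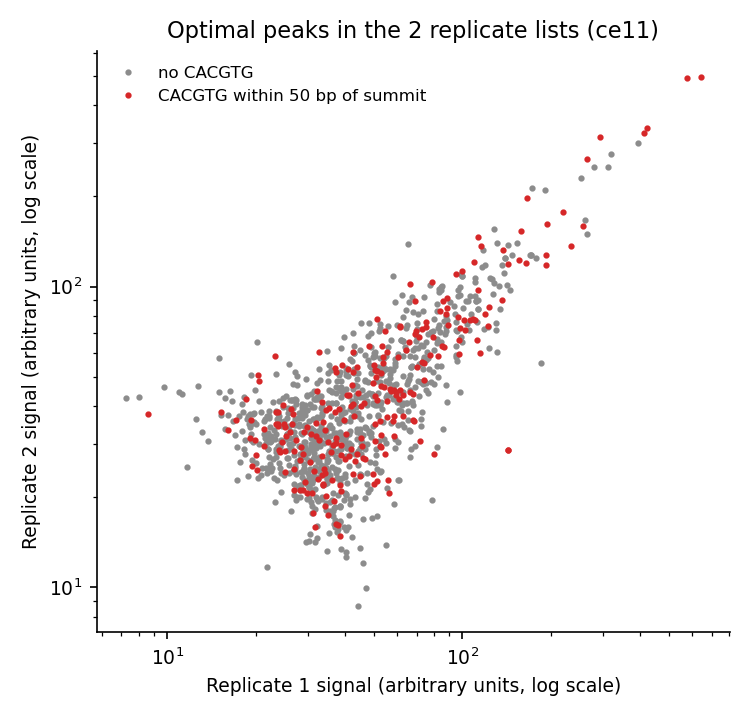
Signal of each optimal peak in replicate 2 against replicate 1, in arbitrary units on log scales, with 1 point per peak and red points for peaks with CACGTG within 50 bp of the summit. The strongest peaks lie near one line, with the top peak at 642 and 497, and the weaker peaks scatter, with rho of 0.61 over 1070 peaks.

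Peaks lay at promoters and in intergenic sequence and avoided coding exons. Of 1076 summits, 539 were in a promoter window, 50.1% (95% interval 47.1 to 53.1) 1.97 times the mean of random placement. The replicates gave 48.6% and 49.2% (n = 2). Intergenic summits made up 56.8%, 1.67 times the placed mean, and 5′ UTRs held 3.25% against a placed 1.41%. Only 1.30% of summits fell in coding exons, against 24.1% by placement, and 0.836% in 3′ UTRs, against 3.39%. Introns of protein-coding genes held 29.3% of summits against 33.3%. The two-sided permutation test of the promoter share gave p = 0.0002, the smallest possible, and so did those of the intergenic, coding exon and UTR shares. For introns the permutation p was 0.006. The shares other than that of promoters were added after the data were examined. The median distance from a summit to the nearest protein-coding start was 824 bp, with quartiles at 253 and 2125 bp, and 76 summits were more than 5 kb away.

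Peaks were also close to genes for small and other non-coding RNAs. Summits lay within 200 bp of a snoRNA gene in 31 peaks, 16.3 times the placed mean, and of an snRNA gene in 11 peaks, 18.5 times the placed mean. For tRNA genes the count was 16, 4.62 times the placed mean, and for miRNA genes it was 6, 4.35 times. The largest count, 211 peaks or 19.6%, was near genes annotated only as ncRNA, 5.15 times the placed mean. For lincRNA genes it was 15, 4.31 times. Pseudogenes, with 1 peak against a placed share of 3.64%, and piRNA genes, with 6 peaks against 2.68%, had fewer peaks nearby than placement gave. For all of these, permutation p-values adjusted over 14 annotation classes were at most 0.0074. These classes of RNA genes were added after the data were examined and were tested in the optimal list only. Because placement covered the whole chromosome, these ratios include the general preference for sequence outside coding exons.

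Chromosome X held 2.01 times the share of peaks that its genes would give, while chromosome V held 0.565 times its share. On X there were 296 summits, 27.5% (95% interval 24.9 to 30.3), where 13.7% of protein-coding genes and 17.7% of the sequence lie. The replicates' own lists had 296 and 297 summits there. Chromosome V had 152 summits, 14.1%, against 25% of genes. Chromosome III had 178 summits, 16.5% against 13.2% of genes, and chromosome IV had 148, 13.8% against 16.4%. Exact binomial tests adjusted over 6 chromosomes gave 6.5e-32 for X, 8.3e-18 for V, 0.0037 for III and 0.026 for IV, while I and II did not pass. Against sequence length in place of genes, the X excess was 1.56-fold, with an exact binomial p of 1.6e-15.

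**Figure D3:**
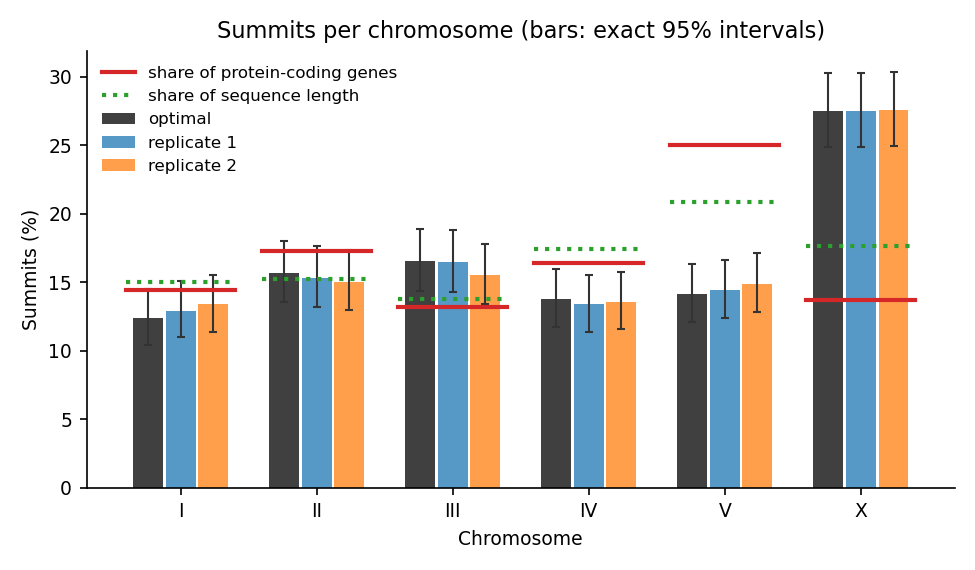
Share of summits in percent on each chromosome for the optimal list and for the strongest regions of each replicate, with exact 95% intervals as error bars. Red lines mark the share of protein-coding genes and green dotted lines the share of sequence length; on X all 3 bars, at 27.5% to 27.6%, stand above both lines.

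The E-box CACGTG was concentrated at summits. It occurred within 50 bp of the summit in 237 of 1076 peaks, 22% (95% interval 19.6 to 24.6), against a mean of 1.58% in the flanks. Peaks with the word only at the summit outnumbered those with it only in the left flank 21.4 times, exact McNemar p = 7.4e-56. Replicate 1 gave 20.3% and replicate 2 gave 19.1% (n = 2). Of 473 CACGTG sites within 500 bp of a summit, 257 were within 50 bp and 91 within 10 bp. The genome holds 17729 CACGTG sites on these chromosomes, and 1.34% as many peaks carried one at the summit. Peaks with CACGTG amounted to 2.39% of the sites on X and to 0.802% to 1.37% on the other chromosomes, while the share of peaks with CACGTG was 19.9% on X and 19.7% to 28.9% on the others.

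Stronger peaks carried the E-box more often. The 216 strongest peaks had CACGTG in 31.5% and the 215 weakest in 15.3% (95% interval 10.8 to 20.9), Fisher's exact p = 9.9e-05. The same comparison gave 30.6% against 13% in replicate 1 and 28.7% against 13% in replicate 2.

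**Figure D4:**
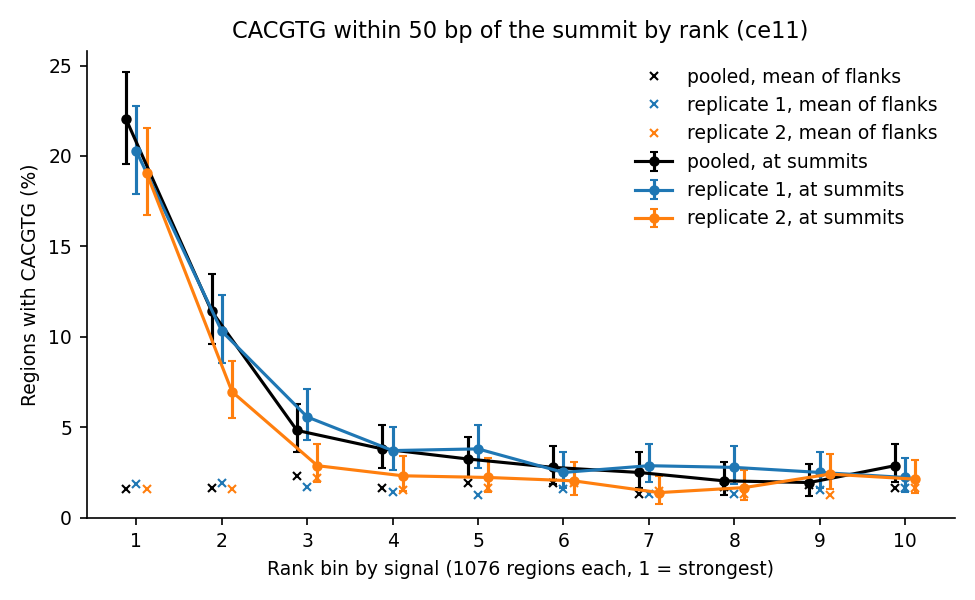
Share of regions with CACGTG within 50 bp of the summit, in percent, against rank bins of 1076 regions by signal, for the pooled list and each replicate, with exact 95% intervals as error bars and crosses for the mean of the flanks. The share falls from 22% in the first pooled bin to 11.4% in the next and comes close to the flanks in the later bins.

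Among the 10 E-boxes of the form CANNTG, CACGTG stood apart. CACATG was at the summit in 9.76% of peaks and in the left flank in 3.62%, with an adjusted p of 1.9e-07 in the exact McNemar test. CAGCTG, at 3.53% against 1.49%, and CAAGTG, at 5.48% against 3.16%, also passed, with adjusted exact p of 0.0087 and 0.028. The other 6 E-boxes did not pass. In the scan of all 2080 6-mers, 556 were higher and 435 lower at summits, and those lower were led by A- and T-rich words such as AAAATT. The mean G and C content was 49.6% at summits and 35.6% in the left flank, which moves many words at once. The first 6 words of the higher group were GAGAGA, in 35.1% of peaks against 7.25% of flanks, CACGTG, AGAGAG, ACGCAG, CGTCTC and GACGCA, the last in 21.5% against 1.86%. With 8-mers the first word was AGACGCAG, in 171 peaks against 3 flanks.

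A promoter peak was found for 614 of 19973 protein-coding genes, 3.07%. The replicates' own lists gave 598 and 615 genes, with 409 shared. Of the 539 promoter peaks, 103 lay in the windows of 2 or more genes, so a peak does not single out 1 gene. Some promoter peaks also had a summit within 200 bp of a small RNA gene. Among the genes named below, these were the peaks of eif-2Bgamma, cox-6A, sdha-1 and fbxa-83, which need not belong to the protein-coding gene. Of the genes fixed in advance, mdl-1 had a promoter peak, and mxl-1, mxl-2, mxl-3, mml-1, klu-1 and unc-119 had none.

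Genes for cytosolic ribosomal proteins had promoter peaks more often than other genes. Of 80 such genes, 16 had a promoter peak, 20% (95% interval 11.9 to 30.4), against 3.01% of other genes, from 16 separate peaks. When each peak was given only to the gene with the nearest start, 9 of 80 remained, against 2.51% of other genes. Against the background of genes with one of the 20000 strongest pooled regions, the share was 24.6% and that of the others 10%. The strongest were at rps-1, with a signal of 194, rpl-3, also 194, and rpl-14 and rps-12, both 124. Only 1 of the 16 genes had CACGTG at its peak, rpl-14. Fisher's exact test gave an adjusted p of 3.4e-08, and the replicates gave 16 and 17 genes. Other growth-related lists did not pass in the optimal list. Translation factors had 4 of 39 genes with a peak, and in replicate 2's list 5 of 39, which passed with an adjusted exact p of 0.025. Those of the optimal list were led by iff-2, a gene for eIF5A, at peak rank 68, and eef-1A.2 with a signal of 154. After them came eif-2Bgamma with 110 and eif-3.C with 52.2. The eif-2Bgamma summit lay 928 bp from the start of that gene and within 200 bp of an snRNA gene. Ribosome biogenesis and RNA polymerase I had 1 of 24, lpd-7, whose peak also lies in the promoter window of a ribosomal protein gene. Aminoacyl-tRNA synthetases had 1 of 31, ears-2, and the proteasome 1 of 31, rpn-11.

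Genes of developmental timing and of autophagy also carried promoter peaks more often. Among 13 heterochronic genes, 4 had one, 30.8% (9.09 to 61.4). They were nhl-2, a microRNA cofactor gene, with a signal of 216, ain-1, which encodes a GW182-type protein of the microRNA complex, with 185, lin-14, a transcription factor gene, with 67.6, and lin-28, an RNA-binding protein gene, with 56.1. Among 26 autophagy genes, 4 had one, 15.4% (4.36 to 34.9). They were the Atg8 homologues lgg-2 and lgg-1, with 121 and 78.1, epg-7 with 106 and atg-9 with 82.6. The adjusted p of Fisher's exact test was 0.0051 for the heterochronic genes and 0.034 for autophagy. The heterochronic call ended in the narrower promoter window, where the adjusted exact p was 0.11, and among the stronger peaks, at 0.083. Both calls ended against the background of genes with one of the 20000 strongest pooled regions in their promoter window, with adjusted exact p of 0.059 and 0.22.

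The network of bHLH-Zip factors had a promoter peak at 3 of 8 genes, 37.5% (8.52 to 75.5), with an adjusted p of 0.011 in Fisher's exact test. They were mdl-1 itself, hlh-11 with a signal of 187 and hlh-30, the TFEB gene, at peak rank 297. The call rested on mdl-1, since without the peaks around mdl-1 and unc-119 it was 2 of 8 genes with an adjusted exact p of 0.070, and it also ended, at 0.088, against the background of genes with a strong pooled region. Among 35 bHLH factors 4 had a peak, hlh-11, hlh-30, hif-1 with 88.5 and its partner aha-1 with 83.6, and the list did not pass, with an adjusted exact p of 0.067. It passed in 2 of 8 other settings, the narrower promoter window, at 0.035 in the same exact test, and the stronger peaks, at 0.012. With the nearest start only, 3 of 35 genes remained, at 0.16 in that test. There aha-1 dropped out, because its peak's summit lay 15 bp from another gene's start and 339 bp from its own.

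Histone genes had promoter peaks at 7 of 72, 9.72% (4 to 19), but from only 5 separate peaks, since paired histone genes share a promoter. The strongest were at his-37 with a signal of 191, his-35 and his-41 at 59.9 each from the same peak, and his-72 at 59.0. The last encodes the replacement histone H3.3, which the symbol pattern takes in with the replication-dependent genes. The adjusted p of Fisher's exact test was 0.034. The result depended on the replicate, with 6 genes in replicate 1's list and 2 in replicate 2's, where the share of 2.78% was below the 3.08% of other genes. In replicate 1's list the adjusted exact p was 0.063, so neither replicate passed alone. Among the stronger peaks 1 of 72 genes remained, 1.39% against 1.55% of other genes, which turned the direction. The call also ended in the wider promoter window, at an adjusted exact p of 0.086, and with the nearest start only, at 0.12. It held against the background of genes with one of the 20000 strongest pooled regions in their promoter window. Only 10 of the histone genes were in that background. Of these, 7 had a peak, 70% against 10.1% of other genes, with an adjusted exact p of 0.00027.

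Chemoreceptor genes had few promoter peaks. Of 1218 chemoreceptor genes, 3 had a promoter peak, 0.246% (0.0508 to 0.718) against 3.26% of other genes, with an adjusted p of 7.2e-12 in Fisher's exact test. They were srh-2 with a signal of 293, srh-17 with 97.8 and srv-7 with 52.3. F-box and BTB genes had 3 of 358, fbxb-58 with 118, fbxa-83 with 71.1 and fbxb-85 with 55.9, with an adjusted exact p of 0.034, and the call ended with the nearest start only, at 0.12, among the stronger peaks, at 0.18, and against the background of genes with a strong pooled region, at 0.85. Cuticle collagens had 1 of 175, col-63 with 58.2, and did not pass, with an adjusted exact p of 0.12, while in replicate 1's list 0 of 175 passed at 0.049. Nuclear hormone receptors had 13 of 274, 4.74%, led by nhr-32 with 262, nhr-1 with 162, nhr-48 with 140 and nhr-49, a regulator of fat metabolism, with 95.8, and did not pass, at 0.26 in the same exact test. Of 63 homeobox ceh genes 1 had a peak, ceh-38 with 105.

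Metabolic lists did not pass the threshold in the optimal list, and some passed under other choices. The tricarboxylic acid cycle had 3 of 20 genes, sucl-1 with 75.8, the citrate synthase gene cts-1 with 66.7 and the succinate dehydrogenase gene sdha-1 with 62.8. Oxidative phosphorylation had 4 of 33, cox-5A with 135, cox-6A with 57.8, atp-1 with 55.5 and cyc-2.1 with 53.3. Both had an adjusted p of 0.067 in Fisher's exact test. The tricarboxylic acid cycle passed in 3 of 8 other settings, with 5 of 20 genes in replicate 2's list and an adjusted exact p of 0.0029, and at 0.038 and 0.033 in the narrower and wider promoter windows. Oxidative phosphorylation passed with the nearest start only, at an adjusted exact p of 0.047. Glycolysis and gluconeogenesis had 2 of 26, the hexokinase gene hxk-3 with 142 and the lactate dehydrogenase gene ldh-1 with 49.6, and it passed only in the wider promoter window, with 5 of 26 and an adjusted exact p of 0.020. Insulin and TOR signalling had 2 of 28, the FOXO gene daf-16 with 95.3 and the AMP-activated kinase gene aak-2 with 76.1. Fatty acid and lipid metabolism had 2 of 33, nhr-49 and acs-2 with 69.2, and the vacuolar ATPase 2 of 21, vha-12 with 76.0 and vha-16 with 51.3.

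No list of tissue markers passed in the optimal list. Neuron markers had 2 of 20, egl-21 with 86.1 and rgef-1 with 70.2, and passed only in the wider promoter window, with 4 of 20 and an adjusted exact p of 0.033. There were peaks at 1 of 22 germline markers, cgh-1 with 75.8. Markers of intestine (15 genes), hypodermis (18), pharynx (13) and body wall muscle (19) had 0, and so did 24 DAF-16 target genes, 32 genes of the cell cycle and DNA replication and 40 lysosome genes. The exact upper 95% bounds for the lists at 0 ran from 8.81% for the lysosome to 24.7% for the pharynx, all above the 3.07% of all genes, so a share below the average cannot be seen in lists of this size.

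**Figure D5:**
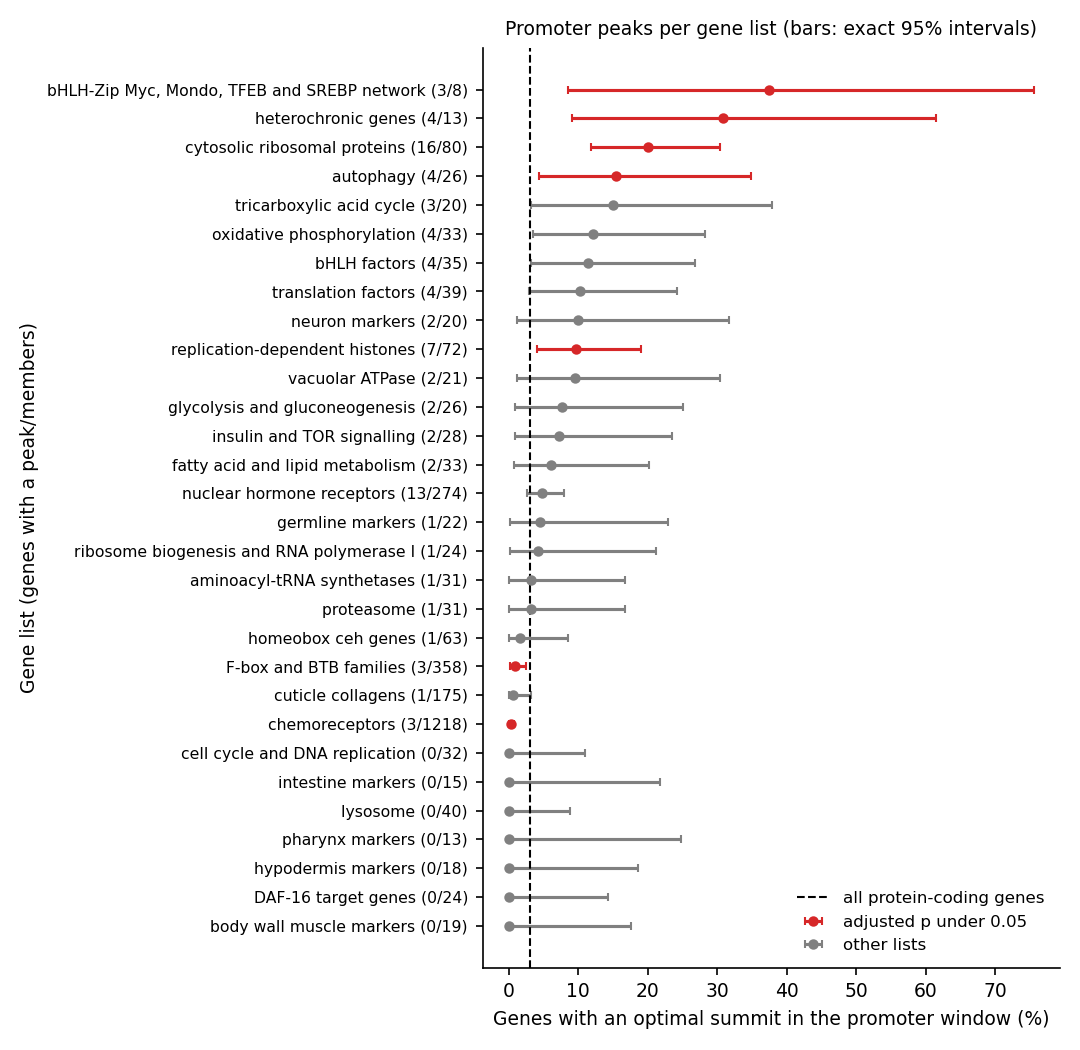
Percent of genes with an optimal summit in the promoter window for each of 30 gene lists, with exact 95% intervals as bars and the number of genes with a peak over members beside each name. Red points mark the 7 lists with an adjusted p under 0.05, and the dashed line marks the 3.07% of all protein-coding genes.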

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

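The tests of explanations for chromosome X were chosen after the share of peaks there was seen. Those below the authors' threshold were chosen after the data were examined. The tests on the tagged protein and its gene were chosen before the data were examined. Their rules did not include the percentiles of regions below the threshold.

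In the pooled list CACGTG was enriched below the authors' threshold, in regions that are not in the optimal list. At ranks 1077 to 2152 it lay within 50 bp of 11.4% of summits (95% interval 9.59 to 13.5), against a mean of 1.67% in the flanks. At ranks 2153 to 3228 the share was 4.83% against 2.32%, and at ranks 3229 to 4304 it was 3.81% against 1.67%. Exact McNemar tests against the left flank gave p = 7.3e-23, 0.0021 and 0.0099, not adjusted over the rank bins. Base composition at summits was not examined in these regions, so its part in the smaller excesses is unknown. The replicates' own lists gave 10.3% and 6.97% at ranks 1077 to 2152. At ranks 2153 to 3228 replicate 1 had 5.58%, exact McNemar p = 6.1e-07, while replicate 2 had 2.88%, exact p = 0.79, so replicate 2 showed no enrichment there. At ranks 3229 to 4304 they had 3.72% and 2.32%, exact p = 0.0010 and 0.041.

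The tagged protein and the peaks around its gene were weighed because 1 label names KLU-1. If KLU-1 had been precipitated, CACGTG was predicted not to be enriched, yet peaks with it only at the summit outnumbered those with it only in the left flank 21.4 times, and the 17 optimal summits lie around mdl-1 and none around klu-1, so the tables argue against that explanation. Extra transgene copies may raise the background at mdl-1. Its window held 33 pooled regions, at the 99.8th percentile of genes, above the bound of 95 set beforehand for extra copies. However, 17 of these are the optimal peaks themselves, which binding would also give. The 16 below the threshold were at the 79.0th percentile, a value that the rule set beforehand did not use. Copy number and binding therefore cannot be told apart. At unc-119 the 21 regions, all below the threshold, were at the 92.8th percentile by all regions and the 94.5th by those below the threshold, short of the bound of 95 set for the test, so extra copies there stay open. Whether MDL-1 binds its own native promoter stays open, and no biological explanation was tested, since the samples form 1 group.

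The excess of peaks on X was set against 3 technical explanations. Without the peaks around mdl-1 and unc-119, X still held 26.3% of summits (95% interval 23.7 to 29.1) against 13.7% of genes, which argues against the transgene's locus as the whole source. X holds 21.7% of intergenic bases, below the lower bound of 24.9% for its share of peaks, so the amount of intergenic sequence does not account for all of it either. The lowest-ranked 10000 pooled regions lay on X in 18.6% of cases (17.8 to 19.3), below the share of the optimal peaks. A background that raised the signal on X would also move regions there up the ranking. The weakest regions alone therefore cannot exclude it. The excess over intergenic sequence could not be resolved in every class of peaks. X held 24.9% of peaks with CACGTG (95% interval 19.5 to 30.9) and 19% of those with GACGCA (14.2 to 24.7). Both intervals include 21.7%, so they neither show nor exclude such an excess, though both lie above the 13.7% of genes. Peaks with CACGTG were not separated from the other peaks, of which X held 28.2%, Fisher's exact p = 0.32. Among peaks with neither word the X share was 31.1% (27.5 to 34.8). A binding preference for X is a candidate hypothesis, with the control's coverage of X untested and no biological explanation tested.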

How the results depend on the processing

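Of 55 values of 9 results recomputed under other choices of window, peaks, control and background, 50 kept their direction, their side of the threshold or their size, and none reversed. The count of 6-mers higher at summits, 556, became 292 words with 8-mers, which tests other words. The 614 genes with a promoter peak became 309 with only the stronger peaks, which are fewer by construction. The 7 gene lists past the threshold became 3 against the background of genes with one of the 20000 strongest pooled regions, where chemoreceptors, ribosomal proteins and histones passed. The percentile of the mdl-1 window went from 99.995 to 100 with 5 kb to each side, and with each replicate's own list it was 99.995 and 99.9975. With each replicate left out in turn, the promoter share was 48.6% to 49.2%, the X excess 2.01 to 2.02-fold and the CACGTG share 19.1% to 20.3%. Agreement between replicates ran from 52.0% with the number of regions doubled to 73.8% with 538 regions, and cannot be computed with 1 replicate. Among single lists, ribosomal proteins and chemoreceptors passed in 8 of 8 alternatives, with adjusted p from 4.1e-09 to 0.0054 and from 1.6e-17 to 0.0011 in Fisher's exact test. Histones reversed to 1.39% among the stronger peaks and, with each replicate left out in turn, ran from 2.78% without replicate 1 to 8.33% without replicate 2; the values of 1.39% and 2.78% were below the share of other genes, and the cause was not tested. Across 14 lists that passed in any setting, 88 values kept their call, 12 fell below the threshold in the same direction, 10 rose past it and the 2 histone values reversed, also below the threshold. No paired analysis was possible because the 2 replicates form 1 group. Read depth, which would set how many weak sites can be seen, is unknown.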

Other observations

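The analyses of GACGCA, of peaks without CACGTG and of small RNA genes were chosen after the data were seen, and so were the genes named here.

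Peaks near small RNA genes included several known families. Among 18 annotated genes for the SL2 spliced leader RNA, which is trans-spliced to downstream genes of operons, 4 had an optimal summit within 200 bp (sls-2.1, sls-2.2, sls-2.4 and sls-2.8), with signals from 144 to 191. Peaks within 200 bp of miRNA genes included mir-52, mir-53 and mir-56 of the mir-51 family. Of 16 peaks near tRNA genes, 11 were on X, where 45.1% of tRNA genes lie, a share that an exact binomial test did not separate from that of the genes, with p = 0.077. Of 31 peaks near snoRNA genes, 2 had CACGTG, and of 11 near snRNA genes, 0 had it.

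Peaks with CACGTG held GACGCA slightly less often than the other peaks. It was found at 16.5% of summits with CACGTG and at 22.9% of those without, odds ratio 0.664, Fisher's exact p = 0.039, not adjusted for the choice of this comparison. Peaks with GACGCA were less often on X, 19% (95% interval 14.2 to 24.7) against 29.8% of the others, exact p = 0.0011, while peaks with neither word were more often there, 31.1% against 22.1%, exact p = 0.0013. Of the 839 peaks without CACGTG, 14.5% held CACGCG at the summit against 0.834% in the flanks, and 10.3% held CACATG against 3.99%.

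Most peaks lacked CACGTG, 78.0%, and several other words were as frequent at summits, among them GAGAGA in 35.1% of peaks, AGAGAG in 31.2%, ACGCAG in 22.5% and GACGCA in 21.5%. Peaks with GACGCA only at the summit outnumbered those with it only in the left flank 17.2 times. Among 76 other words of the same letters the median of this ratio was 1.92 and the highest 8.31, for GCAGAC. Words that share a longer run of bases with GACGCA, such as ACGCAG at 16.9, were left out of the 76. Words that overlap it by fewer bases, GCAGAC among them, were kept. Base composition would raise words of the same letters alike. GACGCA was picked as a leader of the scan by these same counts, so its ratio may be overstated. Its place above the other words was partly fixed by that choice. The comparison therefore cannot decide how much of the excess comes from composition, which stays open. Noise that falls at random is argued against. Of replicate 1's strongest regions without CACGTG, 64% (95% interval 60.7 to 67.2) overlapped one of replicate 2's. In 100 random placements at most 1.75% did. The overlap cannot tell MDL-1 binding from other signal that recurs in both libraries. Replicate 1's regions without CACGTG were shared less often than its regions with CACGTG, at 75.2%, Fisher's exact p = 0.0017. Whether MDL-1 itself binds at the peaks without CACGTG, and what brings it there, stays open, since no other factor's peaks were analysed here. The shares in promoter windows, 51.3% without and 46.0% with CACGTG, were not separated by Fisher's exact test, p = 0.16.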
